A study of Mus musculus with 7 samples.

How the data were processed

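The data were whole-number counts for 55417 gene symbols in 7 libraries of RAW264.7 cells. Total RNA was prepared with a TIANGEN kit and made into TruSeq Stranded Total RNA libraries read as 150 bp pairs, per the labels' protocols. The submitters' processing notes name Trim Galore and Salmon, without versions or roles, and the build hg38. That build is human whereas the symbols are mouse, so no coordinates are given. The mouse annotation, the strand setting and whether the deposited counts are rounded Salmon estimates are not given in the sources used here. If they are estimates, reads shared by near-identical genes were divided by a model.

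Samples were grouped by hairpin as the labels name them. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Genes were kept by filterByExpr with the 3 groups (13329 genes), scaled by TMM and fitted with 1 mean per group over all 7 libraries, which leaves 4 residual degrees of freedom. The robust quasi-likelihood test compared the mean of both hairpins with shNT, each hairpin with shNT, and the hairpins with each other. P-values were Benjamini-Hochberg adjusted within a comparison, with a threshold of 0.05. CPM values used TMM-scaled library sizes. Total counts ran from 16548648 to 18401060 per library, and the common biological coefficient of variation was 13.8%. Counts of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 15.5 to 44.9). None was therefore another library of its group sequenced again. Libraries made from the same RNA or culture were not excluded.

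In the design fixed before the data were examined, 36 gene lists were written, of which 33 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes were Dpep2, the 12 largest increases and 12 largest decreases passing the threshold in the averaged and both single comparisons in 1 direction, with a mean of at least 5 CPM, hairpin and shNT libraries not overlapping, and no clone, model or pseudogene names. Up to 4 members per list with the smallest p past the threshold were also named, or 2 members as values where none passed. Between hairpins, 6 genes per direction were named under the same level and overlap conditions. Some genes that the rule named are not reported here.

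The fits were tested on simulated data with the real means, library sizes and dispersions and 200 changed genes, in 5 simulations of 13093 to 13114 genes. In the averaged comparison 51.3% of 1.5-fold, 83.0% of 2-fold and 94.2% of 4-fold changes were recovered, and 6.3% of calls were false. Between the hairpins recovery was 25.1%, 72.5% and 90.9%, with 8.2% false. For shDpep2.968 against shNT it was 29.6%, 75.5% and 90.9%, with 5.4% false, and for shDpep2.759 28.4%, 74.3% and 90.0%, with 6.8% false. A list raised 1.5-fold was called in all 5 simulations of each comparison, and no other list was called. The simulated genes varied independently, so false calls of lists with correlated members were not tested.

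Alternatives were other size factors, library size alone, other low-count filters, DESeq2, limma-voom, a fit without robust estimation, a replicate block, each library left out in turn, a 2-fold minimum, a fit of all hairpin libraries as 1 group, and fits of the compared groups only. A GC and length correction and a test of the leukotriene list without Dpep2 were added after seeing the data. The correction used per-library splines on values from mouse GENCODE M21 transcripts, which covered 95.7% of tested and 96.0% of changed genes. A further 6 gene lists were written after the first results had been seen.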

Results

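RNA sequencing measured gene expression in RAW264.7 cells, a mouse macrophage-like cell line, carrying short hairpins against Dpep2 or a control hairpin. Dpep2 encodes a membrane-bound dipeptidase known to cleave leukotriene D4. The 7 libraries formed 3 groups: hairpin shDpep2.968 (n = 2), hairpin shDpep2.759 (n = 2) and the control hairpin shNT (n = 3). Total counts per library ran from 16548648 to 18401060. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

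Dpep2 was lower in every library carrying a Dpep2 hairpin. It stood at 22.4 and 17.9 CPM with shDpep2.968 and at 24.9 and 19.5 CPM with shDpep2.759, against 55.6, 60.3 and 52.1 CPM with shNT. Averaged over both hairpins, Dpep2 fell by 1.41 on the log2 scale (SE 0.13, 95% interval -1.68 to -1.13), to 37.8% of the control level (edgeR quasi-likelihood adjusted p = 8.07e-05). The remaining level was 36.0% with shDpep2.968 and 39.6% with shDpep2.759, and the log2 difference between them was -0.14 (95% interval -0.51 to 0.23, adjusted p = 0.725). The related gene Dpep1 had 0 counts in all 7 libraries, and Dpep3 had 2 to 6 counts per library. Of 13 tested genes lying near Dpep2, 1 changed: Esrp2, an epithelial splicing regulator, fell by 1.69 on the log2 scale (adjusted p = 0.020) from a control level of 1.21 CPM. That call was lost without shDpep2.968 replicate 2, shDpep2.759 replicate 2, shNT replicate 2 or shNT replicate 3.

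**Figure D1:**
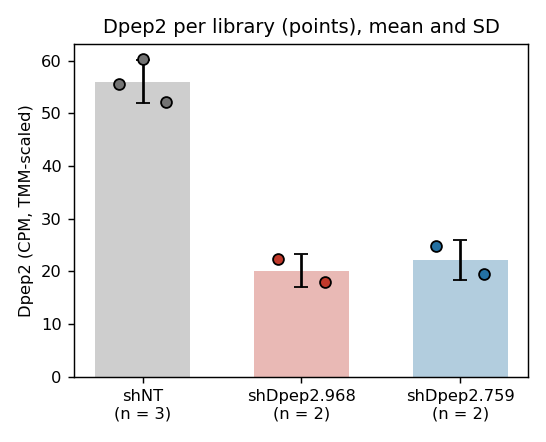
Dpep2 in CPM by group, with points for libraries, bars for means and error bars for the SD. The 4 libraries with a Dpep2 hairpin lay between 17.9 and 24.9 CPM, below the lowest shNT library at 52.1 CPM.

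The first comparison asked which genes changed with Dpep2 knockdown, averaging both hairpins against shNT. Of 26 NF-kB targets 9 rose and 1 fell, 20 of 42 type I interferon response genes and 7 of 17 osteoclast genes rose, and 17 of 24 sterol genes and 10 of 20 fatty acid synthesis genes fell. All 5 lists were called by camera with a preset correlation (adjusted p of 6.96e-09 or lower). With an estimated correlation the fatty acid list alone kept its call (adjusted p = 0.0408, against 0.0827 for the other 4). The cytokine Il1a rose 5.62-fold (log2 fold change 2.49, SE 0.20), from 12.5 ± 3.9 CPM (SD, n = 3) with shNT to 63.9 ± 14.9 CPM (n = 2) with shDpep2.968 and 76.5 ± 2.5 CPM (n = 2) with shDpep2.759. Il1b, another cytokine of that family, rose 3.37-fold. Scd2, a fatty acid desaturase, fell by 1.90 on the log2 scale (SE 0.16), and Aldh1l2, a mitochondrial folate enzyme, fell by 1.81 (SE 0.15).

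The 12 increases named by the rule also held the interferon-induced genes Ifit3b, Ifit1 and Ifit3, which rose 4.66-fold, 3.33-fold and 3.25-fold. Ifit3 and Ifit3b are close paralogs, so the division of reads between them is uncertain. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, rose 3.88-fold, and the guanylate-binding protein gene Gbp3 rose 3.30-fold. Cyria (3.27-fold), Serpinb9b (3.10-fold), Cd83 (3.09-fold), the macrophage elastase Mmp12 (2.93-fold) and the transcriptional regulator Id2 (2.92-fold) completed the 12. Among the decreases, Cth, which makes cysteine from cystathionine, fell by 1.59 on the log2 scale, and the mitochondrial phosphoenolpyruvate carboxykinase Pck2 fell by 1.54. The desaturase Fads2 fell by 1.55, the phosphatidate phosphatase Lpin1 by 1.33 and the 5-lipoxygenase Alox5 by 1.47. Pi16 fell by 1.44, Fam13c by 1.36, the aquaglyceroporin Aqp9 by 1.35 and Prss16 by 1.33. These genes had edgeR adjusted p-values from 6.2e-05 to 0.00326, and all 4 hairpin libraries lay on the same side of all 3 shNT libraries, as the naming rule required.

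**Figure D2:**
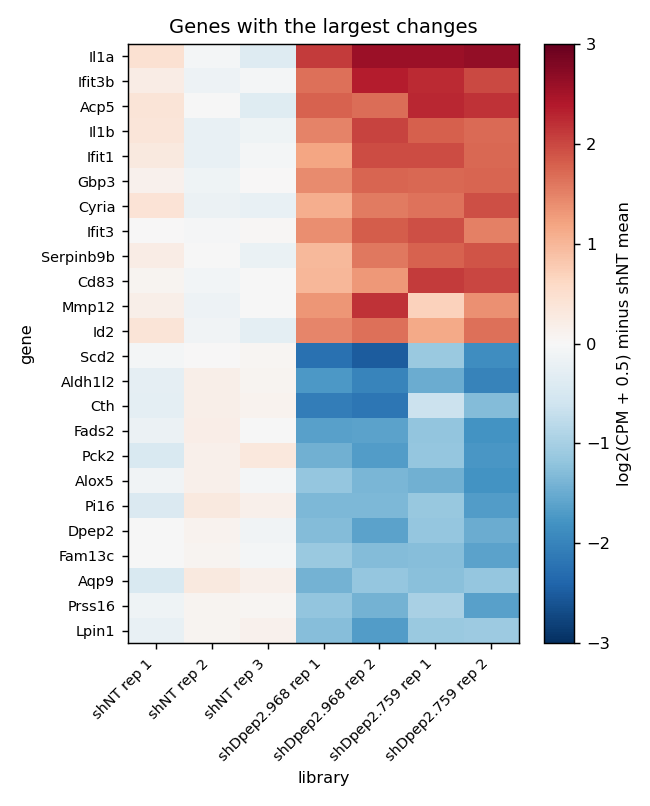
Log2(CPM + 0.5) minus the shNT mean for the 12 largest increases and the 12 largest decreases under the naming rule (rows), in the 7 libraries (columns). The rule required a mean of at least 5 CPM and no overlap of hairpin and shNT libraries, so some larger changes are left out. Red stands for higher and blue for lower values; all 4 hairpin libraries lay above every shNT library for the 12 increases and below every one for the 12 decreases.

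In total 1012 of 13329 tested genes changed, 459 higher and 553 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 3048 had an unadjusted p under 0.05. All 4 hairpin libraries lay on the same side of all 3 shNT libraries for 18.5% of tested genes, against 5.71% by chance. That 5.71% is a mean over all splits. Genes are not independent and the share in other splits was not computed, so its spread is unknown. The count was 492 without shDpep2.968 replicate 2, 356 without shNT replicate 2 and 321 without shNT replicate 3, and 551 with all hairpin libraries fitted as 1 group, where 20 named genes, among them Cth, Gstt1, Lpcat3, Thbs1, Chac1, Itgax, Cfb and Fcgr4, lost their calls. The averaged log2 fold change was correlated with GC content across genes (Spearman -0.25; genes are not independent replicates), and a GC and length correction raised the count to 2106, of which 997 were also among the 1012.

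Genes of sterol synthesis and uptake were lower: 17 of 24 tested members fell and none rose, or 22 lower when adjusted over the list alone (median log2 fold change -0.66, camera adjusted p = 8.31e-26; adjusted p = 0.0827 with an estimated correlation). Insig1, a regulator of sterol synthesis, fell by 1.06 on the log2 scale, and the sterol synthesis enzyme Cyp51 by 0.84. Of 20 fatty acid synthesis genes 10 fell and none rose, or 13 lower when adjusted over the list alone (median -0.43, camera adjusted p = 9.97e-16). This list alone kept its call with an estimated correlation (adjusted p = 0.0408). Fads1, a further desaturase, fell by 0.90. Genes of the LXR target and cholesterol efflux list moved both ways, with 2 higher and 5 lower of 16 and no list call (camera adjusted p = 0.196). The count adjusted over the list alone was 2 higher and 6 lower. The lipid droplet gene Plin2 rose 2.32-fold and Nr1h3, which encodes LXR alpha, 2.32-fold, whereas the sterol exporter Abcg1 fell by 0.81 and the phospholipid acyltransferase Lpcat3 by 0.76.

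Type I interferon response genes were higher: 20 of 42 rose and none fell, or 29 higher when adjusted over the list alone (median 0.48, camera adjusted p = 4.22e-28; adjusted p = 0.0827 with an estimated correlation). Cmpk2 rose 2.24-fold and Oasl2 1.94-fold. Of 28 interferon-gamma-induced GTPase and antigen presentation genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.35e-08; adjusted p = 0.0862 with an estimated correlation). The immunity-related GTPase genes Irgm1 and Igtp rose 2.02-fold and 1.79-fold, and Gbp2 rose 5.78-fold from 0.904 CPM. NF-kB targets had 9 higher and 1 lower of 26, or 10 and 1 adjusted over the list alone (camera adjusted p = 2.49e-10; adjusted p = 0.0827 with an estimated correlation). They held the receptor Tnfrsf1b (2.20-fold) and the NF-kB inhibitor Tnfaip3 (2.11-fold). Of 16 chemokine genes 7 rose and none fell, or 9 higher adjusted over the list alone (camera adjusted p = 3.05e-09; adjusted p = 0.131 with an estimated correlation). Ccl2 rose 1.88-fold, Ccl7 2.14-fold, Cxcl16 1.45-fold, and Ccl12 6.58-fold from 0.556 CPM; the Ccl7 call was lost without shNT replicate 3.

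Osteoclast differentiation genes were higher in 7 of 17 cases and lower in none, or 8 higher adjusted over the list alone (camera adjusted p = 6.96e-09; adjusted p = 0.0827 with an estimated correlation), with the matrix protease Mmp9 up 1.71-fold and Tm4sf19 up 1.91-fold. Pattern recognition genes had 7 higher and 1 lower of 33, or 13 and 1 adjusted over the list alone (camera adjusted p = 8.48e-05; adjusted p = 0.142 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, rose 1.93-fold and Casp4 1.71-fold; Tlr8 (2.20-fold) and Tlr13 (1.67-fold) also passed, but each lost its call without shDpep2.968 replicate 2, shNT replicate 2 or shNT replicate 3. Tlr8 also lost it without shDpep2.968 replicate 1, and Tlr13 without either shDpep2.759 library. Scavenger, complement and phagocytic receptors had 9 higher and 1 lower of 30, or 10 and 1 adjusted over the list alone (camera adjusted p = 8.48e-05; adjusted p = 0.234 with an estimated correlation), among them Cfb (1.97-fold), Cd36 (1.83-fold), Fcgr4 (1.77-fold) and C3ar1 (1.76-fold). Lysosome genes had 6 higher and 3 lower of 40, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.335 with an estimated correlation), and lost the list call without shNT replicate 1 (adjusted p = 0.0547) and by fry (adjusted p = 0.0553). Gpnmb rose 2.65-fold and the proton pump subunit Atp6v0d2 3.14-fold, whereas the lysosomal enzyme Naglu fell by 0.68 on the log2 scale. Atp6v0d2 lost its call without shNT replicate 2, and Naglu without shNT replicate 2 or 3.

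Macrophage identity genes had 3 higher and none lower of 23, or 5 higher adjusted over the list alone (camera adjusted p = 0.00551; adjusted p = 0.121 with an estimated correlation), with the transcription factor Maf up 2.38-fold. Alternative activation genes had 4 higher and 3 lower of 15, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00699; adjusted p = 0.121 with an estimated correlation); Myc rose 2.19-fold and Tgm2 2.36-fold, and the cyclooxygenase Ptgs1 fell by 1.09. That list lost its call with no low-count filter (adjusted p = 0.0772). Immediate early genes had 5 higher and 2 lower of 27, the same numbers as adjusted over the list alone (camera adjusted p = 0.00612; adjusted p = 0.13 with an estimated correlation). The phosphatase genes Dusp1 and Dusp2 each rose 1.89-fold, and Klf2 fell by 0.92. Adhesion and migration genes had 7 higher and 3 lower of 27, as when adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.142 with an estimated correlation), and lost the list call without shNT replicate 3 (adjusted p = 0.064) or with all hairpin libraries as 1 group (adjusted p = 0.0903). Thbs1 rose 3.14-fold, and the integrin gene Itga6 fell by 0.77.

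The leukotriene and prostaglandin list, which holds Dpep2 itself, had 4 lower and 2 higher of 19, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.316 with an estimated correlation). Without Dpep2, a test chosen after seeing the data, 3 of 18 fell and 2 rose, or 4 and 2 adjusted over the list alone, and the list call was lost (camera adjusted p = 0.113; adjusted p = 0.519 with an estimated correlation). The call with Dpep2 was also lost with no low-count filter (adjusted p = 0.0779) and with limma-voom (adjusted p = 0.100). Beside Alox5 and Ptgs1, the prostaglandin D synthase Hpgds rose 1.72-fold. Glutathione and cysteine genes had 5 lower and 1 higher of 27, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.239 with an estimated correlation), and lost the list call with no low-count filter (adjusted p = 0.0580), limma-voom (0.0668) or all hairpin libraries as 1 group (0.0527). The amino acid transporter gene Slc1a4 fell by 1.16, Gstt1 by 1.09 and Cbs by 1.55 from 1.86 CPM; Cbs lost its call without either shDpep2.968 library, shNT replicate 2 or shNT replicate 3. Integrated stress and unfolded protein response genes had 8 lower and 2 higher of 33, or 9 and 2 adjusted over the list alone, with no list call (camera adjusted p = 0.0524). Trib3 fell by 1.22, Asns, the asparagine synthetase, by 0.65, the serine synthesis enzyme Phgdh by 0.69 and Chac1 by 1.04. Phgdh lost its call without shNT replicate 3, and Chac1 without shDpep2.968 replicate 2, shDpep2.759 replicate 2, shNT replicate 2 or shNT replicate 3. Among NRF2 targets 2 of 23 rose, as when adjusted over the list alone. Camera did not call that list (adjusted p = 0.128), whereas fry called it higher (adjusted p = 0.00689). The haem oxygenase Hmox1 rose 1.64-fold and Srxn1 1.35-fold, the second not without shNT replicate 2 or 3.

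Dendritic cell genes had 2 higher and none lower of 9, or 6 higher adjusted over the list alone (camera adjusted p = 1.68e-05; adjusted p = 0.0827 with an estimated correlation). Those 2 were Cd83 and Itgax. Itgax rose 2.49-fold on average but lost its call without shNT replicate 2 or 3. It stood at 8.27 and 7.66 CPM with shDpep2.968 and at 2.30 and 4.57 CPM with shDpep2.759. The value of 2.30 CPM lay below shNT replicate 1 at 2.60 CPM. Of 6 fibroblast and matrix genes 1 rose, or 4 adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.155 with an estimated correlation): Dcn, from 0.546 CPM, whose call was lost in 6 of the 7 fits that left out a library, all except that without shDpep2.759 replicate 2. The fibroblast list lost its call without shDpep2.759 replicate 1 (adjusted p = 0.0735) or shNT replicate 1 (adjusted p = 0.0566), with no low-count filter (0.554), with at least 1 CPM in 2 libraries (0.0621) and with the GC and length correction (0.0567). Neutrophil and lymphocyte markers had 4 tested members each and epithelial markers 0, too few for a list test; Il7r rose 2.67-fold and the immunoglobulin gene Ighm fell by 0.86.

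Histone genes had 2 of 5 higher, as adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.142 with an estimated correlation), with H2bc4 up 2.20-fold. H2bc21 (1.49-fold) lost its call in each of the 7 fits that left out a library. Heat shock genes had none of 14 past the threshold, or 4 higher adjusted over the list alone (camera adjusted p = 0.0355; adjusted p = 0.384 with an estimated correlation), and lost the list call without shDpep2.968 replicate 2, shDpep2.759 replicate 2, shNT replicate 2 or shNT replicate 3, with adjusted p from 0.0519 to 0.141. They also lost it with the GC and length correction (adjusted p = 0.120) and by fry (0.104). The list was called with shDpep2.968 (adjusted p = 0.000889; adjusted p = 0.336 with an estimated correlation) and not with shDpep2.759 (adjusted p = 0.812). Small-RNA and double-stranded RNA genes had 3 higher and 1 lower of 15, or 7 and 3 adjusted over the list alone. The list was not called by camera (adjusted p = 0.0798) but was called higher by fry (adjusted p = 0.0327). Dgcr8 and Eif2ak2 had log2 fold changes of 0.45 and 0.46, and Prkra of -0.46. Those 3 calls were lost without shDpep2.968 replicate 2, shDpep2.759 replicate 2, shNT replicate 2 or shNT replicate 3; Dgcr8 and Prkra also lost theirs without shDpep2.968 replicate 1, and Dgcr8 without shNT replicate 1.

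Camera made no list call for G1/S genes (0 of 35, adjusted p = 0.0583) or G2/M genes (0 of 33, 0.300). It made none for p53 targets (1 of 26, 0.681) or oxidative phosphorylation genes (0 of 36, 0.887). Glycolysis and hypoxia genes (1 higher and 2 lower of 25, 0.842) had none either. The same held for mitochondrially encoded genes (0 of 13, 0.756) and ribosomal protein genes (0 of 44, 0.976). Nor were nuclear long non-coding RNAs (1 of 8, 0.756) or the neighbours of Dpep2 (1 of 13, 0.887) called. Fry, unlike camera, called the G1/S list higher (adjusted p = 0.00689). Adjusted over the list alone, glycolysis genes had 2 higher and 3 lower, long non-coding RNAs 1 of each, and the other 7 lists kept their counts. Median and mean differed in sign for the long non-coding RNAs (0.20 and -0.03) and the neighbours of Dpep2 (0.09 and -0.04). Plk2, a p53 target, rose 1.72-fold, Ndrg1 and Car9 fell by 0.64 and 1.05, and Snhg1 rose 1.33-fold; Car9 lost its call without shNT replicate 2, and Snhg1 without either shDpep2.968 library or any shNT library. Mcm10 had a log2 fold change of 0.31, Kif20a and Bub1b of 0.25 and -0.21, and Sdhd and Cycs of 0.27 and 0.37, none past the threshold. Rps18 averaged 14.7 CPM, and Rpl5 had a log2 fold change of 0.50 that did not pass; ribosomal protein genes share reads with pseudogenes, so their values are uncertain.

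**Figure D3:**
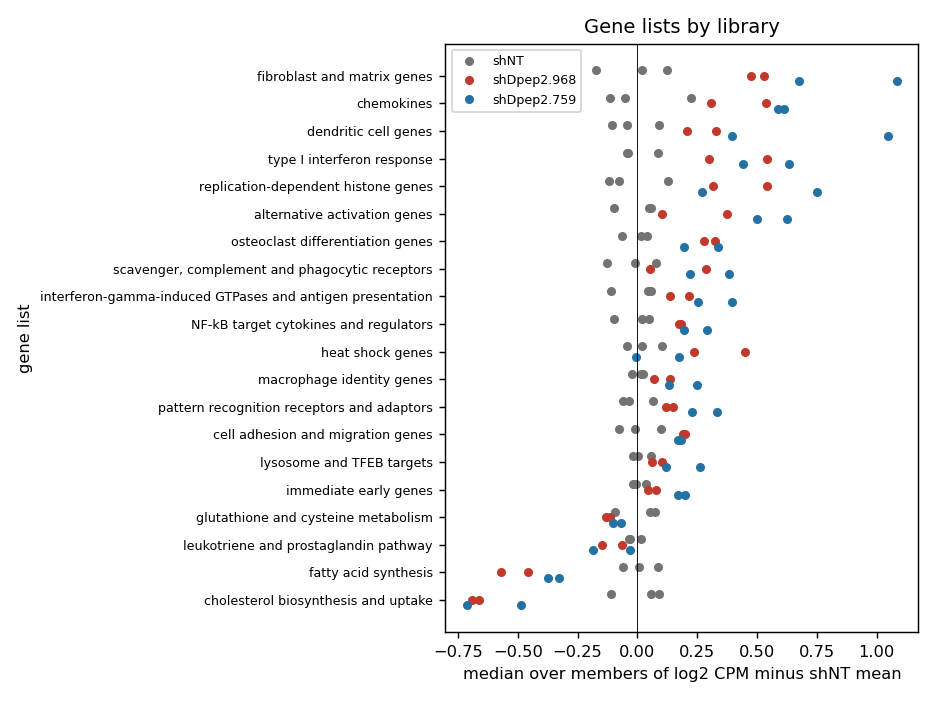
Median over each list's tested members of log2 CPM minus the shNT mean, 1 point per library, for the 20 lists called by camera with a preset correlation. Sterol synthesis medians lay between -0.71 and -0.49 in the hairpin libraries and between -0.11 and 0.09 in the shNT libraries.

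The second comparison took each hairpin alone. With shDpep2.968, Il1a rose 5.14-fold and Ifit3b 4.57-fold, and Scd2 and Cth fell by 2.36 and 2.21 on the log2 scale. With shDpep2.759, Il1a rose 6.15-fold and Ifit3b 4.76-fold, and Scd2 and Cth fell by 1.44 and 0.97. In all 700 genes changed with shDpep2.968 (305 higher, 395 lower) and 630 with shDpep2.759 (363 higher, 267 lower). The first count was 401 without shDpep2.968 replicate 1, 69 without shDpep2.968 replicate 2, 1305 without shDpep2.759 replicate 1, 1309 without shDpep2.759 replicate 2, 218 without shNT replicate 2 and 191 without shNT replicate 3. The second was 299 without shNT replicate 2 and 253 without shNT replicate 3.

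Of the 20 lists called in the averaged comparison, 8 were called with each hairpin alone by camera with a preset correlation. These were the type I interferon, interferon-gamma, NF-kB, chemokine, osteoclast, pattern recognition, sterol and fatty acid lists, with adjusted p from 4.23e-21 to 0.0149 for shDpep2.968 and from 1.59e-28 to 4.83e-06 for shDpep2.759. A further 10 were called with shDpep2.759, and with shDpep2.968 had adjusted p from 0.0596 to 0.196. Of these 10, the hairpins differed for dendritic cell genes (camera adjusted p = 5.68e-05), scavenger receptors (0.000624), macrophage identity genes (0.0107) and alternative activation genes (0.033). The difference did not pass for lysosome (0.206), adhesion (0.236), fibroblast (0.135), histone (0.0939), immediate early (0.156) or leukotriene genes (0.228). The leukotriene list without Dpep2 was not called with shDpep2.759 either (adjusted p = 0.0535). Heat shock and glutathione genes were called with shDpep2.968 (adjusted p = 0.000889 and 0.0177) and not with shDpep2.759 (0.812 and 0.0825), and the hairpins differed for the first (0.000884) and not the second (0.351). The LXR target and cholesterol efflux list, not called on average, was called lower with shDpep2.968 (camera adjusted p = 0.0135, or 0.293 with an estimated correlation). G1/S and G2/M genes were called higher with it (adjusted p = 0.0033 and 0.00501; adjusted p = 0.152 and 0.362 with an estimated correlation), although 0 of 35 and 0 of 33 members passed. The LXR call was lost without shDpep2.968 replicate 1 (adjusted p = 0.0631) and the G2/M call without shDpep2.968 replicate 2 (0.0606). The pattern recognition call with shDpep2.968 was lost without shDpep2.968 replicate 2 (0.0513) or shNT replicate 3 (0.0567), and the leukotriene call with shDpep2.759 without shDpep2.759 replicate 2 (0.0704). The difference for macrophage identity genes was lost without shDpep2.968 replicate 1 (0.0623), and that for alternative activation genes without shDpep2.968 replicate 1 (0.311) or shDpep2.759 replicate 2 (0.167). With an estimated correlation 1 of the 20 lists was called with shDpep2.968, fatty acid synthesis (adjusted p = 0.0462), 0 with shDpep2.759 (lowest adjusted p 0.0583), and no list differed between the hairpins.

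Both hairpins changed 271 genes in the same direction, 148 higher, among them Il1a, Acp5 and Gbp3, and 123 lower, among them Dpep2, Fads2 and Alox5. Abca1, a cholesterol exporter, was the 1 gene called in opposite directions, lower with shDpep2.968 and higher with shDpep2.759. All libraries were also simulated as unchanged, with 1 mean per gene and both comparisons sharing the 3 simulated controls. In 20 simulations 0 to 1 genes were changed by both in the same direction. With no gene changed hardly any is called, so this says little about lists as long as the real ones. Independent lists as long as the real ones would share 16.2 genes (8.3 higher, 7.9 lower), but shared controls make the real lists dependent. Neither number therefore gives the overlap expected from the shared controls alone. Among the genes called with shDpep2.968, 93.1% had the same sign with shDpep2.759, and 92.1% the other way round. The shared controls raise both shares, and no baseline was computed for called genes. Over all tested genes 67.1% had the same sign, against a mean of 62.9% (62.0% to 63.6%) for simulated unchanged groups. Across genes, which are not independent replicates, the hairpins' log2 fold changes had a Pearson correlation of 0.60 and a Spearman correlation of 0.51, against means of 0.38 and 0.37 for simulated unchanged groups. Their covariance was 0.17 against a simulated 0.03. The simulated genes varied independently, unlike genes that share a GC trend within a library, so the simulated range may be too narrow. Part of the excess may therefore still come from the shared controls. The overlap was 171 without shDpep2.968 replicate 1, 53 without shDpep2.968 replicate 2, 104 without shNT replicate 2 and 86 without shNT replicate 3, and the correlation was 0.36 without shDpep2.759 replicate 2.

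**Figure D4:**
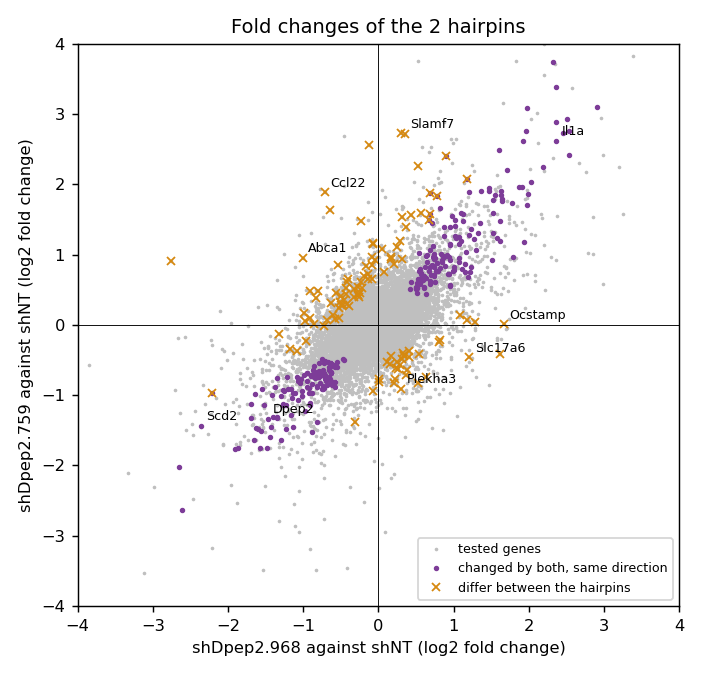
Log2 fold change against shNT with shDpep2.968 (x axis) and shDpep2.759 (y axis), 1 point per tested gene; purple marks the 271 genes changed by both in the same direction and orange crosses the 112 that differed between the hairpins. The axes end at 4 in each direction, which leaves out 30 genes; Ccl22, Slamf7 and Abca1 lie above the diagonal, and Ocstamp and Slc17a6 below it.

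The third comparison set the hairpins against each other. Ccl22, a chemokine, stood at 2.74 ± 0.69 CPM (SD, n = 2) with shDpep2.968 and 16.6 ± 2.7 CPM (n = 2) with shDpep2.759, a log2 difference of -2.59 (SE 0.26, edgeR adjusted p = 0.00156). Also lower with shDpep2.968 than with shDpep2.759 were Slamf7 (-2.37), Abca1 (-1.96), the cytokine Il36g (-1.73), lipocalin Lcn2 (-1.70) and the protease inhibitor Slpi (-1.40). Higher with shDpep2.968 were the vesicular glutamate transporter Slc17a6 (1.67), the osteoclast fusion gene Ocstamp (1.66), Hspa1b (1.38), Slc4a8 (1.35), Plekha3 (1.21) and the urokinase gene Plau (1.11). Hspa1b shares near-identical sequence with Hspa1a, so its counts are uncertain. In all 112 genes differed, 34 higher with shDpep2.968 and 78 higher with shDpep2.759. The count was 13 without shDpep2.968 replicate 1, 6 without shDpep2.968 replicate 2, 33 without shDpep2.759 replicate 1 and 1070 without shDpep2.759 replicate 2. It was 71 without shNT replicate 2 and 28 without shNT replicate 3. Between the hairpins, Slc17a6 lost its call without shDpep2.968 replicate 2, shDpep2.759 replicate 1 or shNT replicate 3. Hspa1b, Slc4a8 and Il36g lost theirs without either shDpep2.968 library or shDpep2.759 replicate 1, Lcn2 and Slpi without either shDpep2.968 library, and Plau without shDpep2.968 replicate 2. The library shDpep2.759 replicate 1 stood apart on the second principal component (24.1% of the variance; -46.7 against -6.1 to 22.2 for the others), with 2.999% of counts in ribosomal protein genes against 1.99% to 2.41%.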

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

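The tests of a single library, of LXR targets, of hairpin RNA sensing and of the genes called from 1 shDpep2.759 library alone were chosen after related results had been seen; the GC and length tests of each pattern used a correction added after seeing the data. The 2 hairpins differed by the edgeR test of the difference for 21 of the 119 named genes. Beside the 12 named for it, whose log2 differences (shDpep2.968 minus shDpep2.759) were Slc17a6 1.67, Ocstamp 1.66, Hspa1b 1.38, Slc4a8 1.35, Plekha3 1.21, Plau 1.11, Ccl22 -2.59, Slamf7 -2.37, Abca1 -1.96, Il36g -1.73, Lcn2 -1.70 and Slpi -1.40, there were 9 others. These were Thbs1 -1.51, Cth -1.24, Cd83 -0.90, Tnfrsf1b -0.90, Itga5 -0.86, Lpcat3 -0.83, Tnfaip3 -0.82, Adgre1 -0.79 and Pfkfb3 -0.77.

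By camera with a preset correlation 12 of the 33 lists differed between the hairpins, none of them with an estimated correlation. Median log2 differences were 0.24 for G2/M genes, 0.22 for heat shock genes and 0.12 for G1/S genes. They were -0.38 for dendritic cell genes, -0.38 for ribosomal protein genes and -0.33 for scavenger and complement receptors. The medians were -0.26 for LXR target and cholesterol efflux genes and -0.22 for macrophage identity genes. They were -0.20 for interferon-gamma-induced GTPases, -0.13 for oxidative phosphorylation genes, -0.11 for NF-kB targets and -0.002 for alternative activation genes, whose mean was -0.21 with 2 of 15 members called lower, Ccl22 and Il4ra. Without shDpep2.759 replicate 1 the ribosomal protein and oxidative phosphorylation lists no longer differed (camera adjusted p = 0.965 and 0.906). Ribosomal protein medians were 0.42 in that library and -0.20 in shDpep2.759 replicate 2, and oxidative phosphorylation medians 0.24 and -0.12. The interferon-gamma difference was lost without shDpep2.968 replicate 1 (0.209) or shDpep2.759 replicate 1 (0.319), that for macrophage identity genes without shDpep2.968 replicate 1 (0.0623), and that for alternative activation genes without shDpep2.968 replicate 1 (0.311) or shDpep2.759 replicate 2 (0.167). The NF-kB difference was lost without any 1 library except shDpep2.968 replicate 2 (0.0721 to 0.298).

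The differences between hairpins were weighed against 2 technical explanations. GC content or length, as far as the correction removes it, was not the whole cause, since 110 of the 112 genes stayed called. The correction also raised the count to 522, so smaller differences could pass and a partial contribution was not excluded. Without shDpep2.759 replicate 1, 100% of the 112 genes kept at least 50% of their log2 difference, but a call already needs both libraries to agree, so this decides nothing. Of 1062 genes called from replicate 1 alone and tested in both fits, 32.6% kept that much in replicate 2, and of 33 called from replicate 2 alone 93.9% did in replicate 1, but genes picked in 1 library shrink in another whatever the cause. Whether replicate 1 stands apart for a technical reason therefore stayed open, and differences in hairpin sequence were untested.

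The fall of sterol and fatty acid synthesis genes was not removed by the GC and length correction, which left 27 of 27 lower members called. That correction raised the averaged count to 2106, so smaller changes could pass and a partial contribution of GC content or length was not excluded. It did not rest on 1 library: over all 44 members the hairpin library nearest to shNT had a median of -0.46, below the lowest shNT library at -0.09. An excess of sterols sensed by LXR would raise its direct targets, yet with shDpep2.968 all 5 (Abca1, Abcg1, Mylip, Lpcat3 and Srebf1) were lower. With shDpep2.759 Abcg1 and Srebf1, 2 of the 5, were lower but Abca1 was higher, so there a sterol excess acting through LXR cannot be told apart from other causes. Srebf1 is itself on the fatty acid synthesis list, so with either hairpin its fall is part of the pattern and not separate evidence. A shared batch or culture difference between the hairpin and shNT libraries stayed open, as the labels give no batch, and an effect of Dpep2 loss remains a hypothesis.

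The rise of interferon and NF-kB genes kept 29 of 29 higher members after the GC and length correction. Here too a partial contribution of GC content or length was not excluded. The hairpin library nearest to shNT had a median of 0.27 over 68 members, above the highest shNT library at 0.06. Sensing of hairpin RNA alike in every library would give no rise over shNT, which also carried a hairpin. Sensing that depends on the sequence or dose of a hairpin cannot be told apart from Dpep2 loss, because sequence goes with the group and dose was not measured; the median difference between the hairpins, -0.088, does not test it. An effect of Dpep2 loss may underlie the rise, as a hypothesis.

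Regrouping the libraries at random tested the averaged count, which compares 4 libraries with 3, and the overlap of 2 comparisons that each set 2 libraries against the same 3. Of 100 of the 105 possible splits, 1, the real one, gave as many as 1012 genes, and the highest other gave 653. For genes changed by both hairpins, 1 of 100 gave as many as 271, and the highest other gave 124. No other split run gave as many for either, but this cannot exclude chance. The libraries divide into 4 against 3 in only 35 ways. Other splits also mix unlike libraries in a group, which widens the spread within groups and lowers the count. The splits giving 653 and 369 averaged genes kept the 3 shNT libraries together and mixed the hairpins. Those giving 589, 358 and 151 put shDpep2.759 replicate 1 with the shNT libraries, against the other 3 hairpin libraries.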

How the results depend on the processing

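The GC and length correction and the leukotriene list without Dpep2 were chosen after seeing the data; the other alternatives were planned. Dpep2 stayed lower and past the threshold in all 19 alternatives. Of 2251 comparisons of named genes with an alternative, 2098 kept direction and side of the threshold, 130 lost the call and 21 gained it. The block ended 17 calls (Cxcl16, Cbs, Srxn1, Phgdh, Chac1, Tlr13, Tlr8, Ocstamp, Adgre1, Fcgr1, Dcn, Pfkfb3, H2bc21, Snhg1, Dgcr8, Eif2ak2 and Prkra) and the heat shock list call (adjusted p = 0.0550). The fit of all hairpin libraries as 1 group ended 20 (Cth, Gstt1, Chac1, Lpcat3, Cfb, Fcgr4, Tlr8, Ocstamp, Adgre1, Fcgr1, Itgax, Dcn, Pfkfb3, H2bc21, Snhg1, Dgcr8, Eif2ak2, Prkra, Thbs1 and Itga5). DESeq2 ended those of Dcn and H2bc21, limma-voom those of Eif2ak2, Prkra and, between hairpins, Slc17a6, the fit without robust estimation that of Eif2ak2, and the GC and length correction that of Snhg1. Of 416 for the called lists, 374 kept the call and 42 lost it, 19 of these with an estimated correlation, under which 1 of the 20 list calls held. Fry ended 2, for lysosome and heat shock genes. It also called the G1/S, NRF2 and small-RNA lists higher, which camera did not. Counts of changed members per list kept a similar size in 474 of 628 comparisons and moved in 154. mt-Cytb, never called (log2 fold change 0.30), turned to -0.006 under the block and to -0.019 without shNT replicate 3. Correlations of replicate 1 deviations across genes were 0.071 between the hairpins, -0.24 for shDpep2.968 with shNT and -0.186 for shDpep2.759 with shNT. They gave no sign that replicate numbers pair libraries. Pairing was not excluded, as each pair of groups gives 1 value and GC trends differ between libraries. With the replicate block the counts were 404 averaged, 308 for shDpep2.968, 312 for shDpep2.759, 130 between hairpins and 116 in both hairpins. Replicate 3 exists only in shNT, so the block fits that library by itself and takes it out of the comparisons. With no low-count filter these were 1590, 1443, 1131, 669 and 499, and the correlation 0.47. With the GC and length correction they were 2106, 1672, 1644, 522 and 706, and at 2-fold or more 263, 245, 232, 47 and 90, the last by construction. Fitting all hairpin libraries as 1 group gave 551 averaged. Fitting only the compared groups gave 1350 for shDpep2.968 and 61 between hairpins. Between hairpins DESeq2 gave 376, limma-voom 54 and the fit without robust estimation 63. The cause was not tested. Leaving out 1 library at a time gave 321 to 1468 averaged, 69 to 1309 for shDpep2.968, 253 to 768 for shDpep2.759, 6 to 1070 between hairpins, 53 to 351 in both hairpins, and correlations of 0.36 to 0.70. These fits had fewer samples, and a lone library was assumed to vary like the other groups. At these depths genes near 1 CPM rest on few counts.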

Other observations

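All gene lists and the test below were written after the first results had been seen. Lists with at least 5 tested members not on earlier lists or already named are therefore repeated with those alone. Those members come from the same data that prompted the lists, so the repeats give no independent support. Amino acid genes of the ATF4 response were lower: 14 of 29 fell and none rose, or 16 lower adjusted over the list alone (camera adjusted p = 3.16e-16; adjusted p = 0.145 with an estimated correlation). They held the proline enzymes Aldh18a1 and Pycr1, which fell by 0.70 and 1.84 on the log2 scale, the serine phosphatase Psph (by 0.91) and the transporter Slc7a5 (by 0.41). Of the 7 members not listed or named before, 4 fell (camera adjusted p = 1.38e-06, or 0.0426 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases 2 fell, Cars by 0.40 and Nars by 0.42, or 7 adjusted over the list alone (camera adjusted p = 0.000369; adjusted p = 0.223 with an estimated correlation).

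Siglec, Cd300, Ms4a and Slamf receptors were higher: 8 of 21 rose and none fell, or 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.87e-09; adjusted p = 0.0873 with an estimated correlation). Ms4a7 had a log2 fold change of 3.69 (SE 0.37) from a control level of 0.304 CPM, Siglece of 1.28, Cd300a of 1.02 and Ms4a6d of 0.87. With shDpep2.968 5 rose (median 0.35) and with shDpep2.759 10 (median 0.69), and the hairpins differed (camera adjusted p = 0.000766; adjusted p = 0.386 with an estimated correlation). Of the 20 not listed or named before, 7 rose (camera adjusted p = 1.15e-07, or 0.0426 with an estimated correlation). Of 7 Schlafen genes 4 rose, with Slfn8 at 0.83, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00354; adjusted p = 0.223 with an estimated correlation). Of 12 genes on the plasminogen activator and matrix protease list 5 rose, as adjusted over the list alone (camera adjusted p = 9.6e-05, or 0.145 with an estimated correlation). Among them were the matrix protease Mmp13 at 1.39 and Serpinb2 at 1.17. Serpinb2 encodes an inhibitor of plasminogen activators, not an activator or a protease. The tRNA synthetase and Schlafen lists held no members listed or named before. In the 5 members of the protease list not listed or named before, the list was not called (camera adjusted p = 0.312).

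A fall of the whole integrated stress and unfolded protein response would lower endoplasmic reticulum chaperones too. Their median log2 fold change over 18 genes was 0.15 (SD over members 0.24), with 2 higher (Calr and Dnajb9) and 1 lower (Edem1; camera adjusted p = 0.126), against -0.40 for the amino acid genes. With 3 chaperones not listed or named before, that list was not repeated. A fall of the amino acid genes without the chaperones may be a hypothesis to follow up, which rests on that comparison of medians alone. The difference between the 2 lists was not tested, and the tRNA synthetases were not compared with the chaperones. The GC trend differed between libraries: the Spearman correlation of log2 deviations with GC content was -0.51 in shDpep2.968 replicate 2 and 0.47 in shNT replicate 2.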
